A study of Mus musculus with 6 samples.

How the data were processed

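Messenger RNA was measured by sequencing in whole kidneys of 12-week-old mice, in 3 libraries labelled Tfam f/f and 3 libraries labelled KspCre Tfam f/f. Per the labels' protocols, RNA with an integrity number above 7 and at least 100 ng of material was selected for poly A+ transcripts, made into strand-specific libraries with dUTP and read as pairs of 150 bases. The deposited values are raw counts of reads per gene, with no normalization. Per the submitters' processing notes the tools were FastQC, Trim Galore, STAR 2.4.1d and HTSeq 0.11.0 with genome build mm10. The order and settings of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. Because that strand setting is unknown, genes that overlap a neighbour on either strand are uncertain.

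Each deposited count file held 54146 genes and 5 summary lines. The summary lines, which hold reads without a gene, ambiguous reads and reads aligned to several places, made up 16.0% to 20.4% of the sum of gene and summary lines in the 6 libraries and were left out of library sizes and tests. Reads that aligned to several places were not counted for any gene, so genes with near-identical copies have too few counts. Gene symbols were those given in the deposited count files. Gene positions were taken from GENCODE release M21 of the same build. There, 54079 of the 54146 identifiers were found without their version suffix and 52480 with it.

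Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 17308. Library sizes were scaled by TMM factors, and the groups were compared with the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. A log2 fold change is the libraries labelled KspCre Tfam f/f minus those labelled Tfam f/f, and its standard error (SE) was taken from the fold change and the F statistic. CPM values were computed from the deposited counts with the same factors. Single measures per library were compared with a two-sided exact permutation test, for which 3 against 3 libraries cannot give a p below 0.1.

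Before the data were examined, 32 gene lists, the tests, the alternatives and a rule for naming genes were fixed. The rule names Tfam, Mb21d1 and Tmem173. It adds the 6 largest changes in each direction among called genes with a mean log2 CPM of at least 2 and no overlap between groups, leaving out predicted genes. It also adds, for each list, up to 3 called members with the smallest p, or 1 member where none was called. Members named beside a count of 5 or fewer that fall outside this rule were chosen after their values were seen. Some genes that would be named are not reported here. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with a correlation estimated per list as an alternative, and with fry. The adrenal list had 1 measured member and was not tested as a set.

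The counts of called genes, the named genes and the gene lists were recomputed with other scaling factors, other filters on low counts, the replicate number as a block, and each library left out in turn. DESeq2 1.42.0 and limma voom were run for the counts and named genes, and a minimum fold of 1.5 for the counts alone. The share of mitochondrial mRNAs was recomputed with each library left out and with other definitions of the share. Thinning every library to the total of the shallowest was added after seeing the data. The procedure was tested on simulated counts for this comparison, run on 17308 genes. It recovered 20.9% of 67 genes changed by 1.5-fold, 67.2% of 67 changed by 2-fold and 97.0% of 66 changed by 4-fold, with 5 false calls. A simulated list of 30 genes moved by 2-fold was called, and 0 of 20 unmoved lists were. Simulated genes were drawn independently of each other, with the same dispersion in both groups. The 0 of 20 therefore does not test lists whose genes vary together, nor groups of unequal spread.

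The labels do not state that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Counting intervals cover counting error only. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 63.1 to 164 among those labelled Tfam f/f and 7.09 to 11.7 among those labelled KspCre Tfam f/f, so none was treated as a duplicate.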

Results

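The study compared kidneys of control mice, which carry a floxed Tfam gene without Cre, with kidneys of mice that also carry the Ksp-Cre transgene, which removes floxed sequence in tubule cells. Tfam encodes a protein that packages mitochondrial DNA and starts its transcription. Total counts over genes were 23921849, 34821537 and 19024208 in the libraries labelled Tfam f/f, and 48899266, 48617981 and 30348281 in those labelled KspCre Tfam f/f. Mean depth was higher in the latter (exact permutation p = 0.2, where 3 against 3 libraries cannot give a p below 0.1). All 6 libraries had Ddx3y counts of 49.5 to 82.4 CPM and Xist at 0.132 to 0.334 CPM.

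The targeted gene was checked in every library, and it went against the labels. Tfam (ENSMUSG00000003923.14, chromosome 10, 71225464 to 71238280 in mm10) stood at 30.3, 33.6 and 23.2 normalized CPM in the libraries labelled Tfam f/f, and at 63.1, 63.5 and 61.4 in those labelled KspCre Tfam f/f. The means were 29.0 ± 5.31 and 62.7 ± 1.12 (SD, n = 3 each). Tfam was therefore 2.15-fold higher in the libraries labelled as carrying Cre (log2 fold change 1.11, SE 0.14, adjusted p = 0.00107). The 13 mRNAs encoded by mitochondrial DNA moved the same way. They made up 3.24%, 5.68% and 2.39% of counts in the libraries labelled Tfam f/f and 11.0%, 11.0% and 11.1% in those labelled KspCre Tfam f/f. The mean shares were 3.77% ± 1.71 and 11.0% ± 0.036 (SD, n = 3 each), and the exact permutation test gave p = 0.1, the smallest this design allows. Because of this contradiction, groups are named here only as the libraries labelled Tfam f/f and the libraries labelled KspCre Tfam f/f, and each direction below is between labels, not between known genotypes.

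**Figure D1:**
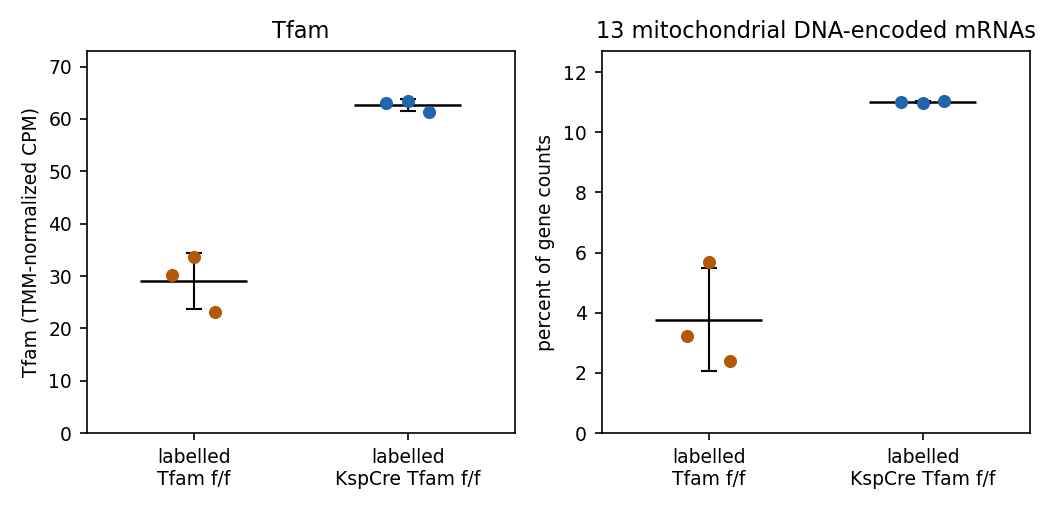
Normalized CPM of Tfam (left) and the share of gene counts from the 13 mitochondrial DNA-encoded mRNAs (right) in each of the 6 libraries. Points are libraries, lines are means and error bars are SD of 3 libraries. All 3 libraries labelled Tfam f/f lie below all 3 labelled KspCre Tfam f/f in both plots.

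A wide part of the kidney transcriptome differed between the labelled groups. Of 17308 genes, 8000 (46.2%) passed the edgeR test with Benjamini-Hochberg adjustment. Of these, 3690 were higher and 4310 lower in the libraries labelled KspCre Tfam f/f, and 1514 and 2287 of them by 2-fold or more. The genes with the largest rise there were Slco1a1, Slc22a7, Pzp, Nccrp1, Akr1c18 and Kcng1. Slc22a7, an organic anion transporter, had 5.30 ± 3.10 normalized CPM in the libraries labelled Tfam f/f and 260 ± 30.6 in those labelled KspCre Tfam f/f (48.3-fold, SE 0.48 in log2, adjusted p = 0.000306). Slco1a1 was 113-fold higher there, and 368-fold without labelled Tfam f/f replicate 2. Without that library Pzp was 72.8-fold higher (45.4-fold with all), and Nccrp1 was 66.2-fold higher without labelled Tfam f/f replicate 1 (40.5-fold with all). The largest falls there were of Vwa5b1, Ostn, Areg, Cdsn, Lcn2 and Sftpd. Lcn2, a marker of tubular injury, had 1011 ± 664 normalized CPM in the libraries labelled Tfam f/f and 2.59 ± 0.302 in those labelled KspCre Tfam f/f (391-fold). Sftpd was 219-fold lower, and 102-fold lower without labelled Tfam f/f replicate 3, with a log2 fold change of -7.78 in all libraries and -8.87 without labelled KspCre Tfam f/f replicate 3. Vwa5b1, Ostn, Areg and Cdsn had 1, 1, 2 and 3 counts over the libraries labelled KspCre Tfam f/f, which gives ratios of 3390 (95% counting interval 607 to 134000), 2250 (403 to 88900), 1390 (385 to 11500) and 1040 (357 to 5070). These ratios are per total count, without TMM factors. The fitted folds, which at such counts depend on the prior count, were 1739, 1149, 854 and 708. The counts of Vwa5b1 and Ostn in that group are all in replicate 2 and those of Areg in replicate 3, so without that library the group has 0 counts and no fold can be estimated. Cdsn was 1161-fold lower without labelled KspCre Tfam f/f replicate 1. The count of genes higher in the libraries labelled KspCre Tfam f/f fell to 2321, 2276 and 2299 without labelled KspCre Tfam f/f replicates 1, 2 and 3, and the count of lower ones to 2822 and 2873 without replicates 2 and 3.

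Mitochondrial DNA-encoded mRNAs were lower in the libraries labelled Tfam f/f, and a part of the nuclear genes of mitochondrial metabolism was. In this paragraph higher and lower are in those labelled KspCre Tfam f/f unless the other label is named. Of the 13 mitochondrial DNA-encoded mRNAs, 12 were higher, with a median log2 fold change of 2.08, and mt-Atp8 did not pass. The examples named by the rule, mt-Co2 (3.91-fold), mt-Co3 (4.24-fold) and mt-Atp6 (4.27-fold, 6.71-fold without labelled Tfam f/f replicate 2), are uncertain because nearly all of their sequence is repeated in a nuclear copy. Among 19 genes for mitochondrial DNA maintenance, 6 were higher, 12 did not pass, and Lonp1, a mitochondrial protease, was lower (2.20-fold). Of 71 nuclear-encoded subunits of the respiratory chain and ATP synthase, 10 were higher and 61 did not pass. The 10 are a smaller share than the 3690 higher among all 17308 tested genes. Adjusted over the list alone 0 passed, and 15 had an unadjusted p under 0.05. Ndufa1 was 1.62-fold and Ndufb4 1.64-fold higher. In the citric acid cycle list, 11 of 20 genes were higher and 9 did not pass. The pyruvate carrier subunit Mpc1 was 1.97-fold higher. In fatty acid oxidation, 15 of 27 genes were higher, 11 did not pass and 1 was lower. Acadm was 3.46-fold and Acads 2.04-fold higher. Of 18 glycolysis genes, 8 were higher in the libraries labelled Tfam f/f, 9 did not pass and Ldha was lower there; Hk2 was 40.7-fold and Pfkp 2.97-fold higher there. Proximal tubule markers were also lower in the libraries labelled Tfam f/f, in 24 of 32 cases. Adjusted over the list alone, the counts higher and lower in the libraries labelled KspCre Tfam f/f were 12 and 0 for mitochondrial mRNAs, 6 and 1 for maintenance, 12 and 0 for the citric acid cycle, 16 and 1 for fatty acid oxidation, and 1 and 8 for glycolysis. Camera called the mitochondrial mRNAs (adjusted p = 1.2e-05), the respiratory chain list (0.000422), the citric acid cycle (0.00168), fatty acid oxidation (0.000239) and, narrowly, the maintenance list (0.0489). With an estimated correlation the adjusted p was 0.53 for mitochondrial mRNAs and maintenance, 0.61 for the respiratory chain and 0.55 for the citric acid cycle and fatty acid oxidation. The glycolysis list was not called (adjusted p = 0.0518). The maintenance call was lost without labelled Tfam f/f replicate 2 or 3 or labelled KspCre Tfam f/f replicate 2 (0.0533, 0.0851 and 0.0563, in a range of 0.0177 to 0.53 over alternatives), and glycolysis was called without labelled Tfam f/f replicate 3 or labelled KspCre Tfam f/f replicate 1 (0.00716 and 0.0473, the range being 0.00716 to 0.53).

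The genes for cGAS and STING, the DNA-sensing pathway in the study's title, were higher in the libraries labelled Tfam f/f. Tmem173, which encodes STING (chromosome 18, 35733679 to 35740554), had 11.6 ± 6.35 normalized CPM there and 2.89 ± 0.473 in those labelled KspCre Tfam f/f (SD, n = 3 each), a 4.0-fold difference (SE 0.39 in log2, adjusted p = 0.00586). Mb21d1, which encodes cGAS (chromosome 9, 78430526 to 78443237), had 1.60 ± 0.048 against 0.611 ± 0.043 (2.59-fold, SE 0.23 in log2, adjusted p = 0.00338). Of the 12 tested genes of this pathway list, Mb21d1, Tmem173, Aim2, Ikbke and Zbp1 were higher in the libraries labelled Tfam f/f, Tbk1, Enpp1 and Trim56 were lower, and 4 did not pass. The counts adjusted over the list alone were likewise 5 higher there and 3 lower. The call of Aim2 was lost without labelled KspCre Tfam f/f replicate 1 (adjusted p = 0.0504, the highest of a range from 0.00129 over alternatives). As a set this list was not called (camera adjusted p = 0.393). Macrophage markers were higher in the same libraries (24 of 25). In labelled Tfam f/f replicates 1, 2 and 3, Tmem173 had 9.84, 6.35 and 18.7 normalized CPM and the macrophage marker Cd68 had 11.05, 7.40 and 18.3. Mb21d1 had 1.54, 1.61 and 1.64 in the same libraries, without the spread of Cd68.

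Interferon, cytokine and cell death genes were partly higher in the libraries labelled Tfam f/f. Of 39 interferon-stimulated genes, 13 were higher there, 25 did not pass and Cmpk2 was lower. Over all 17308 tested genes, 4310 were higher there. Ifit2 was 2.16-fold and Bst2 2.17-fold higher there, and Ifit3b, which is close in sequence to Ifit3, 3.20-fold. Of 26 tested NF-kappaB subunits, cytokines and chemokines, 19 were higher and 7 did not pass. Il1rn, the interleukin 1 receptor antagonist, was 52.2-fold higher (adjusted p = 6.37e-05) and Tnfrsf12a 4.66-fold. Lif was 29.6-fold higher, and 17.6-fold without labelled Tfam f/f replicate 3. Of 16 inflammasome and necroptosis genes, 8 were higher, among them the necroptosis effector Mlkl (3.27-fold), 5 did not pass, and Nlrc4, Il18 and Ripk1 were lower. Macrophage markers were higher in the same libraries, 24 of 25. Adjusted over the list alone, 13 interferon-stimulated, 21 NF-kappaB and 9 inflammasome genes were higher there, with 1, 0 and 3 lower. Camera called the interferon (adjusted p = 0.00194) and NF-kappaB lists (2.17e-05), which both had an adjusted p of 0.53 with an estimated correlation. The inflammasome list was not called (0.159).

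**Figure D2:**
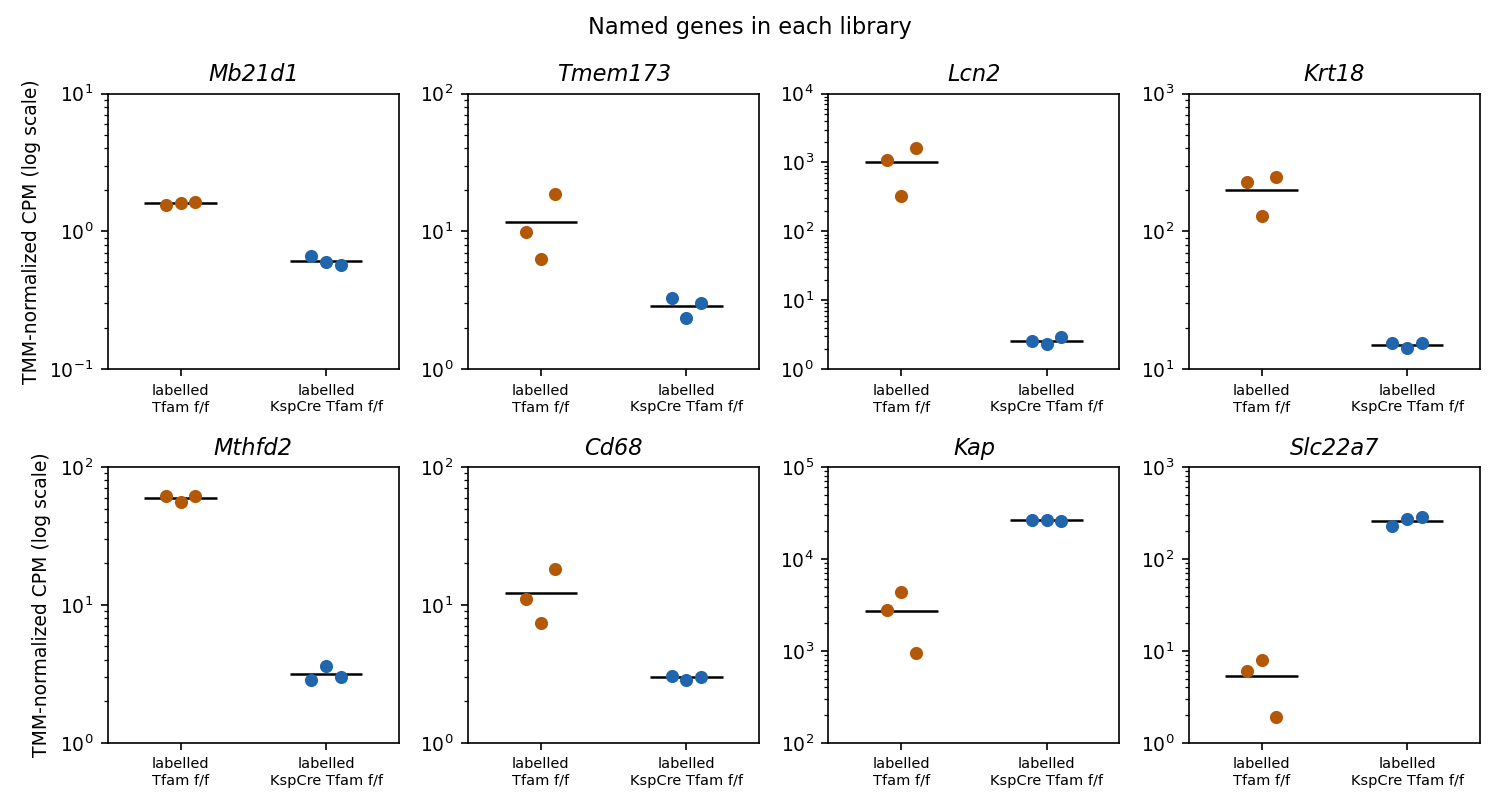
Normalized CPM on a log axis for 8 named genes in each of the 6 libraries. Points are libraries and lines are the mean of 3. Lcn2 lies at 1011 on average in the libraries labelled Tfam f/f and at 2.59 in those labelled KspCre Tfam f/f, and Kap the other way, at 2715 and 26378.

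Stress, cell cycle and injury transcripts were higher in the libraries labelled Tfam f/f. Of 35 tested genes of the integrated stress response and mitochondrial stress, 26 were higher there, 7 did not pass, and Hspd1 and Shmt2 were lower. Mthfd2, a mitochondrial enzyme of one-carbon metabolism, had 60.0 ± 3.33 normalized CPM against 3.15 ± 0.418 (19.0-fold, SE 0.13 in log2, adjusted p = 5.77e-06). Atf5 was 17.0-fold and Nupr1 21.5-fold higher. Of 16 p53 targets and arrest genes, 12 were higher, 2 did not pass, and Perp and Sesn1 were lower; Cdkn1a, the inhibitor p21, was 15.7-fold and Eda2r 9.38-fold higher. Of 20 proliferation genes, 18 were higher and 2 did not pass, with Mki67 6.77-fold and Top2a 5.47-fold. Of 24 tubular injury markers, 23 were higher and Itgb6 did not pass; Krt18 was 13.3-fold and Plaur 11.0-fold higher. Of 42 matrix and myofibroblast genes, 24 were higher, 17 did not pass and Col5a2 was 2.20-fold lower. Fn1 was 6.92-fold and Col1a1 2.72-fold higher. Of 16 immediate early genes, which dissection can induce, 11 were higher and 5 did not pass, with Egr1 20.2-fold and Fosl2 2.69-fold. Macrophage markers were higher in the same libraries. Labelled Tfam f/f replicates 1, 2 and 3 differed among themselves, with 33.71, 5.74 and 88.0 normalized CPM of Fos and 31.65, 9.88 and 138 of the injury marker Havcr1, genes chosen after their values were seen. In those labelled KspCre Tfam f/f the highest were 1.315 and 2.28. On the first principal component the former had scores of 69.9, 37.9 and 107 and the latter -69.7, -72.0 and -73.1. Adjusted over the list alone, 28, 13, 18, 23, 24 and 13 genes of these lists, in this order, were higher there. Camera called all 6, with adjusted p of 1.33e-10, 0.00033, 1.65e-08, 1.72e-08, 8.72e-05 and 0.000422. With an estimated correlation the adjusted p was 0.45 for the stress response and p53 lists and 0.53 for the other 4.

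Most markers of the proximal tubule, distal tubule and intercalated cells were lower in the libraries labelled Tfam f/f, while those of the thick ascending limb and principal cells went both ways. Of 32 proximal tubule markers, 24 were higher in those labelled KspCre Tfam f/f and 8 did not pass, and the counts that follow have the same direction. Kap, an androgen-regulated kidney protein, was 9.72-fold higher and Slc17a3 6.42-fold (9.73-fold without labelled Tfam f/f replicate 2). Of 17 markers of the thick ascending limb, 7 were higher, such as Cldn16 (2.92-fold) and Tmem207 (9.40-fold). Another 5 were lower, among them Cldn19, Ptger3 and Ppp1r1b, and 5 did not pass. Of 15 distal convoluted and connecting tubule markers, 10 were higher, with Klk1 7.72-fold, 4 did not pass and the calcium channel gene Trpv5 was 4.62-fold lower. Of 17 intercalated cell markers, 13 were higher, with Aqp6 4.58-fold and Slc4a9 5.65-fold, 2 did not pass, and Atp6v0d2 and Dmrt2 were lower. Of 15 principal cell markers, 6 were lower, among them Gata3 (2.19-fold) and the sodium channel subunit Scnn1b (1.86-fold), 7 did not pass, and Kcne1 and Aqp4 were higher. Adjusted over the list alone, the counts higher and lower were 26 and 0, 8 and 5, 10 and 2, 13 and 2, and 2 and 6 for these 5 lists in turn. Camera called the proximal tubule (adjusted p = 1.24e-07), thick ascending limb (0.0462), distal (0.0129) and intercalated cell lists (0.000155). Each had an adjusted p of 0.53 with an estimated correlation. The principal cell list was not called (0.0858), but was without labelled Tfam f/f replicate 3 (0.00449, in a range up to 0.61 over alternatives). The thick ascending limb call was lost without labelled Tfam f/f replicate 2 (0.0834, in a range of 0.00388 to 0.53).

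Macrophage markers were higher in the libraries labelled Tfam f/f, lymphocyte and neutrophil markers were higher in part, and those of podocytes and mural cells were lower in part. Of 25 macrophage and dendritic cell markers, 24 were higher there and Csf1r did not pass. Cd68 had 12.3 ± 5.55 normalized CPM there against 2.98 ± 0.0937, and Cd163 was 8.13-fold higher. Of 20 tested T and NK cell markers, 7 were higher, with Lck 4.84-fold, and 13 did not pass. Over all 17308 tested genes, 4310 were higher in the libraries labelled Tfam f/f. Of 12 B and plasma cell markers, 7 were higher, with Igkc 4.64-fold and Jchain 3.48-fold, 4 did not pass and Cr2 was lower. Of 5 tested neutrophil markers, S100a9 (6.13-fold, 3.95-fold without labelled Tfam f/f replicate 3) and Csf3r (3.47-fold, 2.18-fold without the same library) were higher and 3 did not pass. The S100a9 call (adjusted p from 0.00057 to 0.0797 over alternatives) was lost without labelled Tfam f/f replicate 1 or labelled KspCre Tfam f/f replicate 2 or 3, and the Csf3r call (0.00212 to 0.0916) without any of the libraries except labelled Tfam f/f replicate 2. In the other direction, 7 of 16 podocyte markers were higher in the libraries labelled KspCre Tfam f/f, with Dpp4 1.68-fold, 8 did not pass, and Plce1 was lower. The mural cell genes Myh11, Ren1, Mylk, Rgs5 and Cspg4 were higher and 7 of 12 did not pass; Ren1, which encodes renin, was 2.98-fold higher. Among 17 endothelial markers Ehd3 was 1.88-fold higher and 16 did not pass. Of 8 red blood cell transcripts, 7 were higher and Alas2 did not pass; Bpgm was 1.43-fold higher, and the alpha globin genes share sequence and are uncertain. Camera called the macrophage (adjusted p = 6.49e-06), T and NK (0.0129), B and plasma (0.0276), podocyte (0.0166), mural (0.0129) and red blood cell lists (0.00168). With an estimated correlation the adjusted p was 0.55 for T and NK cells and 0.53 for the other 5. Neutrophil (0.219) and endothelial markers (0.102) were not called, but both were without labelled Tfam f/f replicate 2 (0.0157, in a range of 0.0146 to 0.53 over alternatives, and 0.00222, in a range up to 0.61). Adjusted over the list alone, the counts higher and lower in the libraries labelled KspCre Tfam f/f were 0 and 24 for macrophages, 0 and 7 for T and NK cells, 1 and 7 for B and plasma cells, 0 and 2 for neutrophils, 7 and 1 for podocytes, 6 and 0 for mural cells, 1 and 0 for endothelium and 8 and 0 for red blood cells.

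Tissue beside the kidney was looked for with adipocyte and adrenal markers. Of 11 tested adipocyte markers, Plin4 (4.36-fold), Adig, Retn, Cidec and Cfd were higher in the libraries labelled Tfam f/f and 6 did not pass. Cfd, an abundant adipocyte transcript, had 7.23, 47.4 and 9.95 normalized CPM there and 0.986, 0.121 and 5.76 in those labelled KspCre Tfam f/f. Retn was 12.1-fold higher (log2 fold change -3.60), with a log2 fold change of -2.03 without labelled Tfam f/f replicate 2 and -6.28 (77.9-fold) without labelled KspCre Tfam f/f replicate 3, the library with nearly all counts of that group. Its call (adjusted p from 0.0117 to 0.168 over alternatives) was lost without labelled Tfam f/f replicate 1 or 2 or labelled KspCre Tfam f/f replicate 1 or 2. The camera call of the adipocyte list (adjusted p = 0.0147) was lost without labelled Tfam f/f replicate 2 (0.101, in a range of 0.00291 to 0.53 over alternatives, the highest with an estimated correlation). The single adrenal marker tested, Star, did not pass (log2 fold change -0.14, SE 0.25, adjusted p = 0.657). Among 4 Y-linked transcripts Uty was 1.59-fold higher in the libraries labelled KspCre Tfam f/f and 3 did not pass. Its call (adjusted p from 0.00165 to 0.105 over alternatives) was lost without any of 5 libraries, all but labelled Tfam f/f replicate 2, and the list was not called (0.691). Adjusted over the list alone, 5 adipocyte markers, 0 adrenal and 0 Y-linked genes passed.

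**Figure D3:**
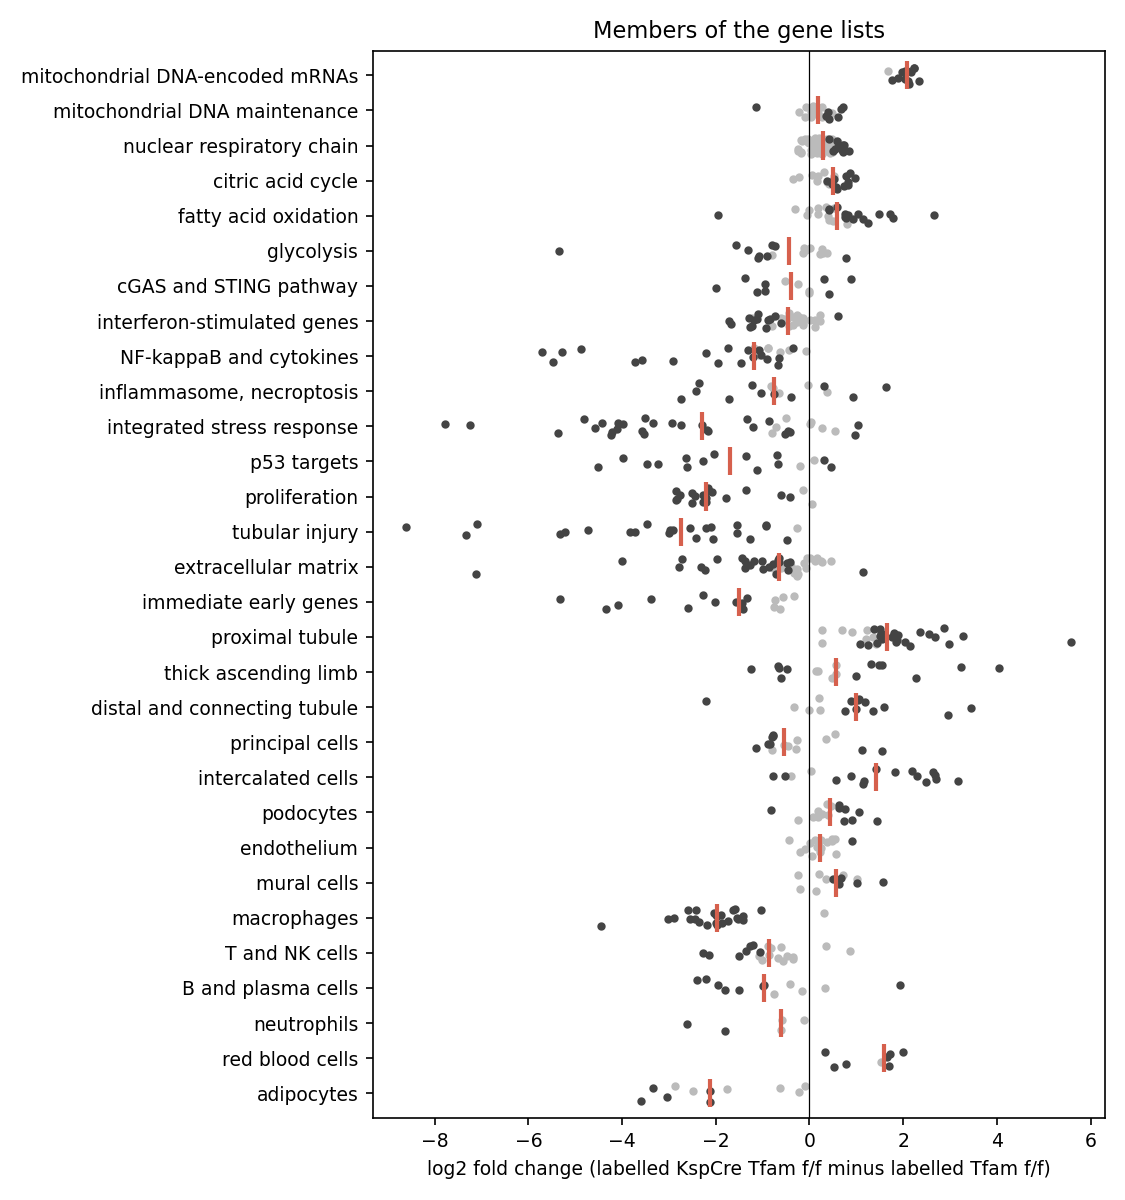
Log2 fold change (libraries labelled KspCre Tfam f/f minus those labelled Tfam f/f) of each tested member of 30 gene lists. Dark points passed the edgeR test, grey points did not, and red lines are list medians. Medians run from -2.73 for tubular injury to 2.08 for mitochondrial DNA-encoded mRNAs, and none changed sign under the other scaling factors.

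As sets, 24 of 31 lists were called by camera with a preset correlation, and 0 with a correlation estimated per list (2 at an unadjusted p under 0.05), which for each of the 24 gave the highest adjusted p of any alternative run. Fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, called 14.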

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

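The test in this part was chosen only after the result was seen. Reads that aligned to more than 1 place, which enter no gene's count, made up 5.73% ± 0.894 of the sum of gene and summary lines in the libraries labelled Tfam f/f and 10.6% ± 0.183 in those labelled KspCre Tfam f/f (SD, n = 3 each). The difference of 4.86 percentage points lies in data outside the main measurement and is the reason this result is listed (exact permutation p = 0.1, the smallest 3 against 3 allows). A candidate source is mitochondrial RNA, since stretches of mitochondrial DNA are repeated in the nuclear genome. Annotated nuclear transcripts repeat over 90% of the 100-base windows of 5 mitochondrial mRNAs and under 10% of those of 6, and the former had a median count per kilobase 0.00879 times that of the latter, which is consistent with reads lost to copies. The low mt-Atp8 and mt-Nd6 have no annotated copy, so other reasons for low counts exist. The median log2 fold change was 2.10 for the 5 and 2.04 for the 6; how much of the 4.86 points such reads account for was not measured, and other repeated sequence stays open.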

How the results depend on the processing

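The alternatives were fixed before the data were examined except the thinning of depth, which was chosen after. Counts of called genes, named genes, gene lists and the mitochondrial share were each run under a part of the alternatives. The share kept its direction in those runs. No named gene or list reversed that was called in the main run or in the alternative. Those called in neither were not checked for a change of sign. Lists were not run with DESeq2, voom or a minimum fold, and the share only with left-out libraries and other definitions. Tfam stayed higher in the libraries labelled KspCre Tfam f/f and past the threshold in every run made for it, with log2 fold changes of 0.97 to 1.25. The difference in the share of mitochondrial mRNAs was 6.56 to 8.20 points with 1 library left out. Genes higher in the libraries labelled KspCre Tfam f/f numbered 2276 to 4652 with 1 library left out, and lower ones 2822 to 4942. At a minimum fold of 1.5 they were 1116 and 1824, fewer by construction. Upper-quartile factors moved the median of all genes from -0.03 to -0.10 and gave 3219 and 4921, and thinned counts gave 3421 and 3936. DESeq2 gave 3993 and 4261 (1 adjusted p was not given) and voom 3776 and 4097. Lists called numbered 0 with an estimated correlation and 14 with fry, against 24. Besides these, the maintenance, thick ascending limb, B and plasma cell and adipocyte lists lost their call under some setting of scaling, filter, thinning, block or left-out library, and the glycolysis, principal cell, endothelial and neutrophil lists gained one. Named genes that lost their call under some setting were Ndufs1, Aim2, S100a9, Csf3r, Slc25a37, Hba-a2, Retn and Uty; the cause was not tested. With the replicate number as a block, 3227 genes were higher and 3586 lower, Tfam had 1.12 and 23 lists were called. The numbers do not pair the libraries: same-number correlations were -0.16, -0.07 and -0.07, and no library correlated best with its own number. In simulated counts 20.9% of 1.5-fold changes were recovered. Thinning to the shallowest library kept 7107 of the 8000 calls, and leaving out 1 library labelled KspCre Tfam f/f kept 5007 to 5128.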

Other observations

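The tests in this part, of families, male-biased genes, labels, cell shares, depth and splits, were chosen after the results were seen. Genes sharing a symbol prefix were grouped into 207 families of at least 10 tested genes, and Fisher's exact test with Benjamini-Hochberg adjustment asked which held more called genes than the rest. This test takes genes as independent, which genes of a family need not be. Its p-values therefore do not measure the spread between libraries. Ribosomal protein genes were higher in the libraries labelled Tfam f/f, with 77 of 91 Rpl genes (adjusted p = 1.75e-30) and 51 of 71 Rps genes (2.37e-14). These prefixes include pseudogenes and kinases. Without those, 43 of 45 Rpl and 32 of 33 Rps genes were higher there, with median log2 fold changes of -1.06 and -1.16. Rpl12 was 4.52-fold and Rps24 3.11-fold higher, and their many processed copies make single values uncertain. Variable segments of antibody genes were also higher there, in 42 of 55 Igkv and 38 of 52 Ighv genes. In the libraries labelled KspCre Tfam f/f, 15 of 24 Slc22a transporters, 11 of 16 Pex genes for peroxisome assembly (12 of 17 with Pex5l, which shares only the prefix) and 10 of 14 histone genes were higher, although proliferation genes were lower there. Most histone mRNAs lack a poly A tail, so their counts in poly A+ libraries are uncertain. Among the families that passed Fisher's test, no median changed sign under the other scaling factors. The rest of the 207 families were not checked for this.

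A hypothesis of weaker androgen response was examined with 12 genes known to be higher in male mouse kidney, a list written after the values were seen, of which 4 are also in the proximal tubule list. Of these, 11 were lower in the libraries labelled Tfam f/f, with Cyp7b1 15.7-fold and Acsm3 8.42-fold. The median log2 fold change was 2.90 against 1.51 for the other proximal tubule markers, a difference of 1.39. Of 5 genes listed as female-biased, Akr1c18 and Cyp2a4 were lower there too, Cyp4a14 was higher and 2 did not pass. Whether each of these 5 is female-biased in kidney was not measured here, so their directions do not weigh on the hypothesis. The list holds genes already seen among the largest changes, such as Slco1a1 and Kap, so this difference does not test the hypothesis, which stays open.

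The libraries labelled Tfam f/f had less Tfam and less mitochondrial mRNA. Genotypes as labelled predict a median log2 fold change of the mitochondrial mRNAs below 0, and it was 2.08, beyond the members' spread, which argues against them. Exchanged genotype labels predict both values on the wrong side in every library, and this held in 6 of 6. Both values were fixed as checks on the labels before the data were examined. The prediction of an exchange was written after they were seen, so it restates them and adds no support beyond them. The letters WT appear in the names of the count files of the libraries labelled KspCre Tfam f/f. The letters MV appear in those of the libraries labelled Tfam f/f. Loss of mitochondria-rich tubule cells alone predicts a like fall of nuclear respiratory chain genes only if both are equally concentrated in those cells. The median of the mitochondrial mRNAs exceeded that of the nuclear genes by 1.80 log2 units, more than the spreads combined. Proximal tubule markers had a median of 1.655, and how each kind of mRNA is shared among cells was not measured. Such a loss therefore stays open. An exchange stays a hypothesis that these data do not settle.

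Proximal tubule markers were lower and macrophage markers higher in the libraries labelled Tfam f/f. A smaller share of proximal tubule cells alone would raise endothelial and macrophage markers alike, and their medians differed by 2.20 log2 units, beyond their spread. Unequal depth is argued against, since 100% of the 48 called members kept their call at equal totals. Without the library with the highest Adipoq, labelled Tfam f/f replicate 2, the median log2 fold change of macrophage markers was -2.27. That library had the lowest macrophage median of its group, so leaving it out could not shrink the difference, and perirenal fat stays open. A change within cells, more macrophages and the genotype may contribute too, and the labels do not settle which.

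Other splits of the 6 libraries were tried. In the real split edgeR called 8000 genes, and 1 of 10 splits gave as many, with 0 in the highest of the others (24 to 263 at an unadjusted p under 0.05). For lists, 24 were called, 1 of 10 splits gave as many, and the highest other gave 22. With 10 splits the share cannot go below 0.1. Every other split mixed libraries of both labels, so the difference between labels widened the spread within its groups. Low gene counts in those splits follow from this mixing, and the splits do not settle whether the grouping arose by luck.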
